A study of Homo sapiens with 192 samples.

How the data were processed

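Single cells of 2 human breast cancer lines, MCF7 and BT-474, were isolated with a single-cell dispenser, and the polyadenylated RNA of each cell was made into full-length cDNA and a sequencing library in a reduced reaction volume, per the labels' protocols. Each of the 192 samples is the library of 1 well, and the labels assign 96 to each line. Replicate numbers follow the order of the samples, and the same number marks the same well position in both lines; the labels name no other origin that such libraries share. The deposited table that identifies the libraries has 192 entries, and 192 of them gave the same line as the sample labels. The line stands there as the plate, and the well positions repeat between the lines, so each line filled its own plate.

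The authors deposited a table of raw read counts per gene made with STAR 2.7.5c and featureCounts 2.0.3, per the submitters' processing notes, with whole numbers in every library. The authors also deposited tables of estimated counts per gene from kallisto 0.46.1 and Salmon 1.3.0, per the submitters' processing notes, and these estimated counts were whole numbers as deposited and were used unchanged. Per the labels, the genome build of all 3 tables was GRCh38.p13; the annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here. The authors' deposited tables of log2 fold changes between the lines carry the column names of DESeq2, whose version 1.32.0 appears in the submitters' processing notes; the libraries, filters and design behind them are not given in the sources used here. In the kallisto comparison only the entries for ACTB and ERBB2 carried a gene name, and only these were read. The p-values of those tables take cells as replicates and are not printed.

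The STAR table was the main table. It holds 38366 genes, of which 35019 matched an identifier of the GENCODE 29 annotation, and 35148 had a symbol; identifiers outside that annotation held 0.389% of the counts. It has 1 per-sample column that matches no sample label, which was not used, and 1 BT-474 library had no matching column, leaving 96 MCF7 and 95 BT-474 libraries. A library was kept at 50000 counts or more in genes and 2000 genes or more with at least 1 count. Libraries under 2000 counts were called near-empty. No 2 kept libraries had identical columns, and the highest Pearson correlation between any 2 was 0.901. Among genes with 1000 or more counts, 210 had the same counts as another gene identifier in every library, 81 of them outside GENCODE 29; such copies cannot be told apart by these counts.

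The labels name no culture, so each line is 1 sample and cells are not replicates. No p-value, standard error or count of changed genes was made from cells for a difference between the lines. Permutations of libraries within 1 line and a probability over wells appear only among the closing observations and describe these libraries. Counts of the kept libraries were summed per line and divided by the summed total and given as CPM, counts per 1000000 counts. The log2 ratio of MCF7 over BT-474 has a 95% interval from the exact (Clopper-Pearson) binomial interval of both sums. These intervals cover counting error only: the reads are PCR copies without molecular identifiers and are not independent molecules. A sum under 3 counts over a line was set to a floor of 3 counts over that line, and the ratio is then a bound. Such ratios are written as at least where the sum is 0, and the intervals use the sums as counted. Genes with 5 CPM or more in at least 1 line were called measured.

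Fixed gene lists, 29 in number with 847 entries, were written before the data were examined. So were the tests, the filters, the rule for naming genes and the alternatives, except those stated below to be chosen after the data were seen. Each list was scored by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Lists outside the central 95% of random lists are described as higher in 1 line. The 95% interval of a list median is an order-statistic interval over its members. For the lists with 3 or 5 measured members it is the full range of the members, whose coverage is under 95%. The lists with under 3 measured members, cancer testis antigen genes and immune cell genes, were not scored. Gene order for regions came from GENCODE 29 on GRCh38: windows of 25 consecutive measured genes, in steps of 5 genes, were ranked by their median log2 ratio. The Spearman correlation of each kept library with the summed profile of its own line (without that library) and of the other line was taken across 3563 genes as a check of the labels.

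For comparisons between cells, kept libraries were thinned without replacement to 1000000 reads, which retained 48 MCF7 and 58 BT-474 libraries. Variability is the log2 ratio of the squared coefficient of variation to a lowess trend on the mean, for genes with a mean of 50 CPM or more. Co-variation of a list is the mean pairwise Pearson correlation of log2(CPM + 10) of its members with a mean of 10 CPM or more, with its percentile among 10000 matched random lists. The 3 quantifications were compared per library by the Pearson correlation of log2(CPM + 1) across shared genes.

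Named genes are the 12 with the highest and the 12 with the lowest log2 ratio among genes with 50 CPM or more in the higher line, detection in 50% or more of its kept libraries and a symbol; up to 4 members of each list with the largest absolute ratio; ERBB2, ESR1, PGR, GATA3, FOXA1, KRT8, KRT18 and KRT19; the 10 most variable genes of each line; the 5 genes with the highest and the 5 with the lowest ratio between quantifications; and up to 4 genes per window. Genes named outside this rule are said to be so.

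The alternatives were the kallisto and Salmon tables, TMM scaling (edgeR 4.0.16), median-of-ratios scaling, equal weight of libraries, other filters on libraries and genes, thinned libraries, mitochondrial totals left out, plate columns 1 to 6 and 7 to 12 alone, a pseudocount, other window sizes, and other transformations and correlation measures for co-variation. Chosen after seeing the data were the removal of the libraries nearer to the other line, the removal of libraries with over 20% of counts in mitochondrially encoded genes from the comparisons between cells, the removal of the library with the most reads of a gene from its variability, and the thinned count of detected genes as an alternative for depth. The scripts were tested on simulated counts drawn from these libraries. In the simulated line comparison over 7728 genes the median error was -0.02 on the log2 scale for genes changed 2-fold, -0.01 at 4-fold and 0.01 at 8-fold. In the simulated variability ranking over 3101 genes, 10 of 10 genes made more variable were the 10 highest. In the simulated co-variation over 7728 genes, a list with a shared factor had a mean correlation of 0.462. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3 were used.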

Results

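The transcriptomes of individual MCF7 and BT-474 cells were measured to follow single-cell full-length RNA sequencing at a reduced reaction volume in 2 breast cancer lines. MCF7 is an estrogen receptor positive human breast cancer line without ERBB2 amplification and with an intact TP53 gene. BT-474 is a human breast cancer line that expresses hormone receptors, carries an amplified ERBB2 gene and has a mutated TP53 gene. Count columns were matched to 96 MCF7 and 95 BT-474 libraries, each made from 1 well. The cells were untreated. With no separate cultures named, neither line had replicates, and every difference below describes these libraries. Each line filled its own plate, so differences between the lines cannot be told apart from differences between the plates.

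Kept libraries of both lines held about 10000 detected genes, and mitochondrially encoded genes, which code for subunits of the respiratory chain, took a larger share of the counts in BT-474. The median was 10045 detected genes in MCF7 (range 6839 to 11599, SD 957 over 57 libraries) and 10170.5 in BT-474 (range 8107 to 11683, SD 568 over 72 libraries). The mitochondrially encoded genes held a median of 7.49% of counts in MCF7 (range 5.02% to 28.2%) and 11.8% in BT-474 (range 7.15% to 17.6%). MCF7 replicate 3 and replicate 30, with 20.02% and 28.2%, were the 2 libraries above 20%. The total count per kept library was 107464 to 4831678 in MCF7 (median 1928681) and 174878 to 3307022 in BT-474 (median 1467047.5). After thinning to 1000000 reads, the medians were 9640 detected genes in 48 MCF7 libraries and 9943.5 in 58 BT-474 libraries. The 57 kept MCF7 libraries were 59.4% of those with a column (exact binomial 95% interval 48.9% to 69.3%) and the 72 kept BT-474 libraries were 75.8% (65.9% to 83.99%). Of the libraries not kept, 36 of 39 MCF7 and 22 of 23 BT-474 libraries were near-empty. MCF7 replicate 70 was left out with 796609 counts because these fell on 1937 genes.

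**Figure D1:**
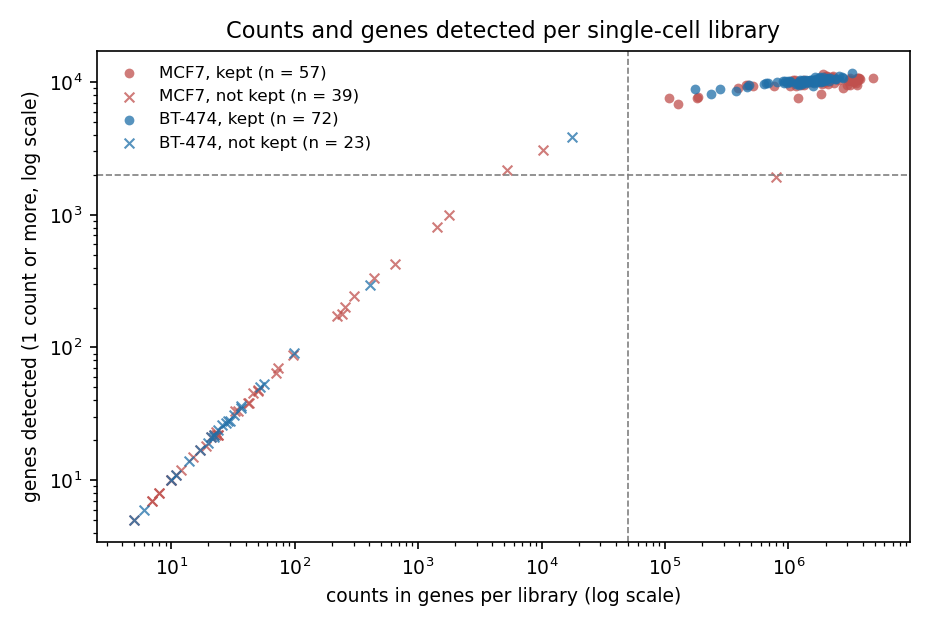
Total counts (log scale) against genes detected for each library with at least 1 count, MCF7 and BT-474 in separate colours. The 57 kept MCF7 and 72 kept BT-474 libraries lie above 50000 counts and 2000 genes, and most of the others hold under 2000 counts.

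All 72 kept BT-474 libraries were nearer to the BT-474 profile, and 51 of 57 kept MCF7 libraries were nearer to the MCF7 profile. The other 6 libraries labelled MCF7 were nearer to BT-474. In 5 of these 6 (replicates 80, 31, 34, 56 and 10), the 12 MCF7-high genes named below, among them LGALS1, RAB31 and MSMB, together stood between 0.065% and 2.15% of the median level of the other 51 MCF7 libraries. The 12 BT-474-high genes, among them MGP, ANXA1 and MUCL1, stood in the same 5 libraries between 37.6% and 83.9% of the median BT-474 level. The sixth library, replicate 58, held 67.7% of the MCF7-high level and 31.4% of the BT-474-high level. For comparison, the MCF7-high genes reached at most 5.10% in any BT-474 library (median 0.425%), and the BT-474-high genes at most 7.13% in the other 51 MCF7 libraries (median 0.267%). The BT-474 libraries themselves held between 26.8% and 676% of the median BT-474 level. Both sets of genes were named from sums that include the 6 libraries. The Spearman correlations of those 5 libraries with the BT-474 profile were 0.797 to 0.902, against 0.573 to 0.646 with MCF7. Values without these 6 libraries stand beside each result that they move by over 1.5 times.

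**Figure D2:**
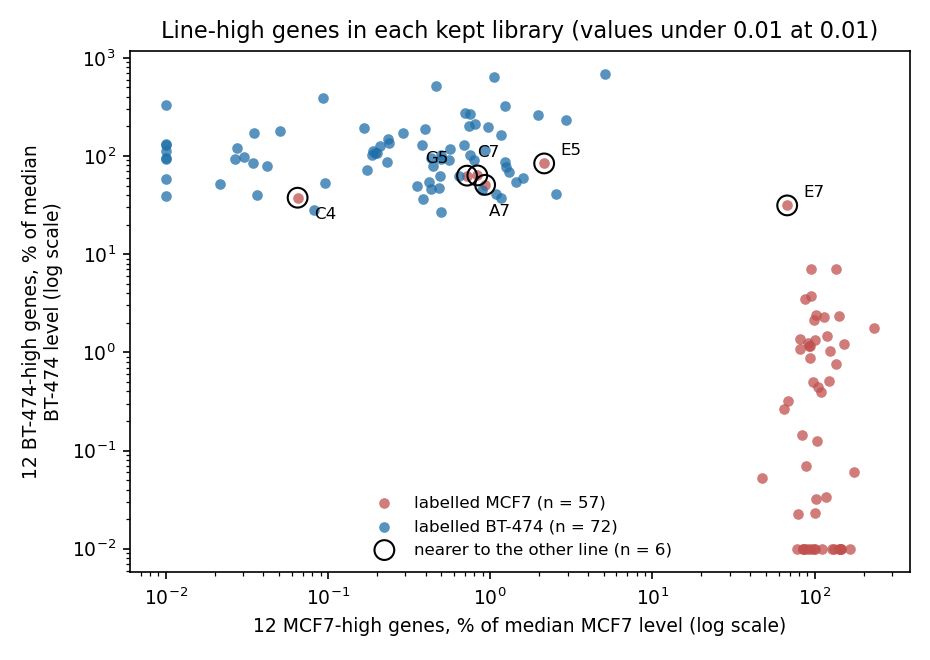
Level of 12 MCF7-high genes and of 12 BT-474-high genes in each kept library, as percent of the median level in the line (log scales, values under 0.01 drawn at 0.01). Of the 57 libraries labelled MCF7, 5 of the 6 ringed ones lie among the BT-474 libraries, and the sixth, in well E7, lies at 67.7% and 31.4%.

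LGALS1, ALDOC and RAB31 were among the genes with the highest ratios in MCF7. The extracellular lectin LGALS1 (ENSG00000100097) stood at 372 CPM in MCF7 and 0.634 CPM in BT-474, 587-fold higher (log2 ratio 9.20, 95% interval 8.85 to 9.56). The aldolase isoform ALDOC was 585-fold higher (9.19, interval 8.63 to 9.82), and RAB31, a small GTPase of vesicle transport, 122.9-fold (6.94, interval 6.84 to 7.04). RAB31 was detected in 56 of 57 MCF7 libraries and in 56 of 72 BT-474 libraries. The heparan sulfate endosulfatase SULF1 had a log2 ratio of 8.62 (interval 7.98 to 9.35), the secreted protein MSMB 8.56, the syntaxin-binding protein STXBP2 9.47 (interval 8.59 to 10.53), the endocytosis protein FCHO1 9.19, KRTCAP3 7.49, the oligosaccharyltransferase subunit TUSC3 6.32 and the glycogen phosphorylase PYGL 6.22. IFT57, a part of the intraflagellar transport machinery, had 10454 counts in MCF7 and 1 count in BT-474 (log2 ratio 11.64 at the floor of 3 counts, interval 10.74 to 18.53). TMCO1, a calcium channel of the endoplasmic reticulum, had 14620 counts against 2 (12.12, likewise at the floor, interval 10.85 to 15.75). With the kallisto and Salmon tables its log2 ratio was 6.64 and 6.51, and that of FCHO1 was 8.40 and 7.67. In plate columns 1 to 6 and 7 to 12 alone, LGALS1 was at 10.07 and 8.39, FCHO1 at 10.04 and 8.44, SULF1 at 8.34 and 9.64 (interval 8.09 to 11.92) and KRTCAP3 at 7.24 and 8.26.

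MGP, SLC40A1 and TM4SF1 were among the genes with the highest ratios in BT-474. The matrix protein MGP (ENSG00000111341) was 94.98-fold higher in BT-474 (log2 ratio -6.57, interval -6.69 to -6.45), at 460 CPM against 4.84 CPM. The iron exporter SLC40A1 was 65.7-fold higher (-6.04), the membrane protein TM4SF1 44.5-fold (-5.47), the secreted phospholipase PLA2G2A 44.03-fold (-5.46) and the calcium-dependent phospholipid-binding protein ANXA1 34.9-fold (-5.12). NEDD4L, a ubiquitin ligase, had a log2 ratio of -5.11, PDLIM3 -5.00, HGD, an enzyme of tyrosine breakdown, -4.91, the secreted protein BPIFB1 -4.90, ARHGDIB, a regulator of Rho GTPases, -4.82 and the small mucin-like protein MUCL1 -4.81. ECM1P2 (-4.73) is annotated as a pseudogene and its counts are uncertain. Without the 6 libraries nearer to BT-474, the log2 ratio was -9.37 for MGP, -12.26 for ANXA1, -8.67 for NEDD4L, -5.58 for PDLIM3, -10.99 for HGD (interval -14.62 to -9.72), -7.58 for BPIFB1, -6.78 for ARHGDIB, -6.02 for MUCL1 and -9.85 for ECM1P2. SLC40A1, PLA2G2A and TM4SF1 then had 0 counts in MCF7 and were at least 2576-fold, 2101-fold and 1868-fold higher in BT-474. In plate columns 1 to 6 and 7 to 12 alone, ANXA1 was at -7.57 and -3.92, BPIFB1 at -6.08 and -3.04, TM4SF1 at -6.52 and -4.60, MGP at -6.07 and -7.998 and MUCL1 at -5.24 and -3.54. All MCF7 counts of TM4SF1 and nearly all of ANXA1 came from the 6 libraries. The spread of these 2 genes between the sets of columns therefore rests largely on those libraries. Most MCF7 counts of BPIFB1, MGP and MUCL1 came from them too, and how far this moved their values was not tested. Of the genes named for their ratio, in their list or in their window, a minority of 48 moved by over 1.5 times in at least 1 of the 2 sets of plate columns. Some of the 48 stood at the floor of 3 counts in BT-474 in both sets. These were OLFML3, EMCN, ACTA2 and LINC00960, with 0 counts there, and IFT57, TMCO1 and IFITM1, among others. Their ratios are bounds that fall with the smaller counts of a set, so such a move need not be a difference across the plate. The histone gene H4C8 went from -2.86 to 0.002 (interval -0.19 to 0.20), no clear difference between the lines.

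By the same rule without those 6 libraries, 11 of the 12 MCF7-high genes remained and the collagen-related secreted protein CTHRC1 (log2 ratio 7.01) came in. Of the 12 BT-474-high genes, 2 remained, ANXA1 and SLC40A1. The vitamin B12 carrier TCN1 then led with 6 counts in MCF7 and 562677 in BT-474 (log2 ratio -16.57, interval -18.01 to -15.45), where the ratio with all kept libraries was -4.13. The glutathione peroxidase GPX1 had 0 counts in 51 MCF7 libraries and 112207 in BT-474, at least 38767-fold higher. PNMT, an ERBB2 neighbour, was at least 7334-fold higher, the lactate dehydrogenase subunit LDHB at least 4874-fold, the lipoxygenase ALOX15B at least 4044-fold and SLC40A1 as given above. The remaining 6 were the chemokine CXCL14 (-11.97, interval -18.86 to -11.08), the serine synthesis enzyme PSAT1 (-11.70, interval -18.59 to -10.80), the aldehyde dehydrogenase ALDH2 (-11.51), ANKRD30A (-11.40, interval -13.67 to -9.85) and the protease KLK12 (-11.22, interval -18.11 to -10.33), with ANXA1 (-12.26). With all kept libraries the log2 ratios of these genes were -3.85 for GPX1, -3.31 for PNMT, -4.43 for LDHB, -4.32 for ALOX15B, -1.76 for CXCL14, -4.71 for PSAT1, -4.43 for ALDH2, -4.71 for ANKRD30A and -3.67 for KLK12. CXCL14 stood at -4.27 in plate columns 1 to 6 and turned to 0.52 in columns 7 to 12. As the 51 other MCF7 libraries held 1 count of CXCL14, this turn rests on the 6 libraries.

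The receptor genes used to classify breast tumours parted the lines. ERBB2 (ENSG00000141736, GRCh38 chromosome 17, 39687914 to 39730426), the receptor kinase HER2, was 14.6-fold higher in BT-474, at 461 CPM against 31.6 CPM (log2 ratio -3.87, interval -3.92 to -3.82; -5.29 without the 6 libraries). The estrogen receptor gene ESR1 was 8.56-fold higher in MCF7 (3.10, interval 3.05 to 3.15), with its partner factors FOXA1 at 4.99-fold (2.32) and GATA3 at 3.43-fold (1.78). The progesterone receptor gene PGR was 7.49-fold higher in BT-474 (-2.91, interval -2.96 to -2.85). Keratin genes of luminal epithelium differed less, with KRT8 2.21-fold and KRT18 2.27-fold higher in MCF7 and KRT19 at a log2 ratio of -0.18. TMCO1 overlaps UCK2, KRTCAP3 overlaps IFT172, MGP overlaps C12orf60, ERBB2 overlaps PGAP3 and MIEN1, and KRT8 overlaps KRT18 in the annotation, so their counts are uncertain where strand was not used.

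Across the 9825 measured genes, the Pearson correlation between the lines' log2 CPM was 0.741 (interval 0.731 to 0.749), and 0.657 without the 6 libraries; genes are not independent replicates. The log2 ratio had quartiles of -0.53, 0.06 and 0.72, and 68.2% of genes lay within 1 of 0. Of these genes, 3537 met the expression, detection and naming criteria.

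Genes around ERBB2 stood together as the list with the largest difference. All 18 measured members of the HER2 amplicon list were higher in BT-474, by a median of 11.8-fold (log2 ratio -3.56, interval -3.87 to -3.13, 0th percentile of matched random lists), and by -4.41 without the 6 libraries and -2.79 with equal weight of each library. PPP1R1B, a phosphatase inhibitor, had a log2 ratio of -5.52, the lymphoid transcription factor IKZF3 -4.53, STAC2 -4.24 and PGAP3 -3.91; without the 6 libraries IKZF3 stood at -11.05 (interval -14.68 to -9.78) and PGAP3 at -5.34, and STAC2, at 0 counts in MCF7, was at least 299-fold higher in BT-474. With Salmon PPP1R1B was at -8.36, IKZF3 at -3.35 and STAC2 at -2.53. In the 20q13 amplicon list 19 of 25 members were higher in BT-474 (median -1.03, interval -1.42 to -0.16, 0th percentile), including BCAS1 (-2.92), FAM210B (-2.08) and the mitotic kinase AURKA (-2.05). The endosulfatase SULF2 of the same list was 52.4-fold higher in MCF7 (5.71). In the 17q23 amplicon list 15 of 22 were higher in MCF7 (0.77, interval -0.44 to 1.42, 99.95th percentile), led by the transcription factor TBX2 (3.78), BCAS3 (3.02), the DNA repair helicase BRIP1 (3.003) and the phosphatase PPM1D (1.95); BCAS3 was at 3.75 and BRIP1 at 2.27 with kallisto. The 1q copy gain list had 14 of 19 members higher in MCF7 (0.91, interval -0.24 to 1.83, 99.94th percentile), with ELK4 at 2.62, IKBKE at 2.30, ANXA9 at 2.18 and PRUNE1 at 2.06. In the 9p21 list, with 5 measured members, the median of 0.73 lay inside the random range, with the cell cycle inhibitor CDKN2A at -3.34 (interval -3.51 to -3.17; -4.44 without the 6 libraries), MTAP at -2.19 (-3.05 with kallisto), IFT74 at 1.07 and FOCAD at 1.03.

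Estrogen receptor target genes were higher in MCF7, in 20 of 29 measured members (median 1.09, interval -0.04 to 1.61, 100th percentile). The lysosomal protease CTSD was 9.57-fold higher (log2 ratio 3.26, interval 3.25 to 3.27), CELSR2 10.7-fold (3.43) and the transcription factor FOS 7.59-fold (2.93), while PGR was the list's largest difference in the other direction. The p53 target list was higher in MCF7 in 19 of 23 members (1.19, interval 0.48 to 2.39, 100th percentile). GDF15, a secreted stress cytokine, was 19.1-fold higher (4.25, interval 4.17 to 4.34), the cell cycle inhibitor CDKN1A 13.5-fold (3.76, interval 3.70 to 3.82) and the death receptor TNFRSF10B 7.44-fold (2.90). FAS, another death receptor, had 759 counts in MCF7 and 1 in BT-474 (7.85, interval 6.96 to 14.74), and its log2 ratio was 5.51 with kallisto and 6.36 with Salmon. A single library held 57.7% of the GDF15 reads of the thinned MCF7 libraries. In plate columns 1 to 6 and 7 to 12 alone, GDF15 was at 1.35 and 6.69 and CDKN1A at 2.31 and 4.51.

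Genes of DNA replication and mitosis were slightly higher in BT-474. In the S phase list 27 of 38 members were higher there (median -0.47, interval -0.60 to -0.05, 0.04th percentile), such as the DNA polymerase subunit POLA1 (-2.17) and RAD51AP1 (-1.75), while BRIP1 and UHRF1 (1.53) were higher in MCF7. In the G2 and M phase list 44 of 53 were higher in BT-474 (-0.43, interval -0.81 to -0.31, 0.03rd percentile), such as CKAP2L (-2.25), AURKA and the kinetochore protein CENPF (-1.94), against ANP32E at 2.92. With equal weight of each library the G2 and M phase median was -0.27. Mitochondrially encoded genes were higher in BT-474 in 9 of 13 (-0.55, interval -0.70 to 0.05, 0.545th percentile), led by MT-CO2 (-1.08), MT-ND1 (-1.01), MT-CO1 (-0.70) and MT-CO3 (-0.67).

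Hypoxia and glycolysis genes were higher in MCF7 in 19 of 25 members (median 0.69, interval 0.17 to 1.46, 99.7th percentile), with ALDOC followed by the transcription factor BHLHE40 (4.92), MXI1 (2.62) and the glycolytic regulator PFKFB3 (1.81). Unfolded protein and integrated stress response genes were higher in 15 of 24 (0.64, interval -0.42 to 1.49, 99.54th percentile), with the mTOR inhibitor DDIT4 at 4.15 and the cystine transporter SLC7A11 at 3.23 against PSAT1 at -4.71 and DDIT3 at -2.52; PSAT1 was at -11.70 without the 6 libraries. In plate columns 1 to 6 this list lay inside the random range (96.3rd percentile), as it did with genes of 1 CPM or more (97.3rd percentile).

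Several small marker lists went both ways. Mesenchymal genes had 4 of 5 measured members higher in BT-474 (median -2.94, interval -4.51 to 5.16, 0.365th percentile): TWIST1 (-4.51), the intermediate filament VIM (-4.04) and COL1A1 (-2.94), against COL6A2 at 5.16. Without the 6 libraries VIM was at -6.03, and TWIST1, at 0 counts in MCF7, was at least 512-fold higher in BT-474. ERBB receptors and ligands had 5 of 7 higher in BT-474 (median -0.85, interval -3.87 to 1.61, 2.085th percentile), with EGFR at -1.86 and ERBB4 at -1.67 against the ligand AREG at 1.61. This list turned to 0.22 with kallisto, 1.03 with Salmon and 1.18 among genes of 20 CPM or more, and it lay inside the random range without the 6 libraries (3.06th percentile). Of 3 measured endothelial genes (median 2.29, interval -1.46 to 8.64, 98.7th percentile), EMCN had 1307 counts in MCF7 and 0 in BT-474, at least 398-fold higher (log2 3.98 with kallisto and 4.80 with Salmon), EGFL7 was at 2.29 and ESAM at -1.46; the list lay inside the random range with kallisto (67.95th percentile), with Salmon, in plate columns 7 to 12 and among genes of 1 CPM or more.

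Lists of epithelial identity and of the immune response lay inside the random range, although single members differed strongly. Of the luminal epithelial genes (12 of 29 higher in MCF7, median -0.12), the secretoglobins SCGB2A2 and SCGB1D2 were 256-fold (7 counts in MCF7, log2 interval -9.32 to -6.95; at least 566-fold, at 0 counts, without the 6 libraries) and 42.5-fold higher in BT-474, and ANKRD30A 26.3-fold. SCGB1D2 had 0 counts in MCF7 and 1661 in BT-474 in plate columns 1 to 6, and 60 and 668 (log2 ratio -3.77) in columns 7 to 12. Among 8 basal and myoepithelial genes (median 0.27), the smooth muscle actin gene ACTA2 had 1111 counts in MCF7 and 0 in BT-474, at least 339-fold higher (log2 5.50 with kallisto and 6.14 with Salmon), ITGB4 was at 3.01, CDH3 at 1.90 and KRT15 at -2.42. This list moved outside the range with kallisto (1.57, 99.7th percentile) and Salmon (1.61, 99.6th percentile). Interferon stimulated genes (12 of 17 higher in MCF7, median 0.44) included IFITM2 at 5.90, the ubiquitin-like ISG15 at 3.09 and IFITM1, with 1564 counts against 1 (8.90, interval 8.002 to 15.79), while MX2 was at -3.63 (-5.15 without the 6 libraries). Antigen presentation genes (6 of 9 higher in MCF7, median 0.22) included the class I genes HLA-B at -5.00 and HLA-C at -4.45, which stood at -7.45 and -10.87 (interval -13.15 to -9.32) without the 6 libraries, HLA-DRB1 at -1.65 and the peptidase ERAP1 at 1.71, which was at 0.25 with kallisto and 0.15 with Salmon.

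Metabolic, stress and housekeeping lists also lay inside the random range. The medians were -0.003 for cholesterol and fatty acid synthesis genes (SREBF1 2.14, HMGCS1 -2.08, FADS2 -1.63, ME1 1.53), 0.51 for immediate early genes (FOSL1 4.35, FOS 2.93, CCN2 2.77, KLF2 -2.57), -0.26 for heat shock genes (HSPA4L 3.20, BAG3 2.93, HSPB1 1.24, HSPA8 -1.05) and -0.10 for S100 and calcium binding secretory genes (S100A8 -6.54, interval -7.86 to -5.49, and S100A4 -3.91; -7.68, interval -14.57 to -6.78, and -4.91 without the 6 libraries). FOSL1 was at 6.83 with kallisto and 6.95 with Salmon. Large ribosomal subunit protein genes had a median of 0.36 at the 97.3rd percentile (97.6th, outside the random range, without the 6 libraries, and 98.1st, also outside it, among genes of 20 CPM or more), and RPL19 (-3.21) and RPL23 (-3.13), which lie near ERBB2 and were at -3.88 and -3.67 without the 6 libraries, went against RPL18A (1.37) and RPL13 (1.07). The medians were 0.27 for small ribosomal subunit protein genes (RPS23 1.498, RPS21 1.39, RPS2 1.12, RPSA 0.98), -0.13 for oxidative phosphorylation genes (NDUFS6 -1.62, NDUFB10 1.495, NDUFA4 -1.41, NDUFS8 -1.03) and 0.36 for replication dependent histone genes (H2AC20 2.497, H2BC9 2.40, H2BC21 1.71, H4C8 -1.35). In the lists with too few measured members, the cancer testis antigen gene CT83 had 3396 counts in MCF7 and 7 in BT-474 (8.79, interval 7.75 to 10.11), and CORO1A of the immune cell list was at -0.30. Some lists inside the random range lay outside it in other settings: immediate early genes in plate columns 1 to 6 (99.4th percentile) and in columns 7 to 12 (99.7th), luminal epithelial genes (1.54th) and replication dependent histone genes (99.4th) in columns 7 to 12, heat shock genes with kallisto (2.16th) and Salmon (2.24th), and S100 and calcium binding secretory genes among genes of 1 CPM or more (0.25th).

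**Figure D3:**
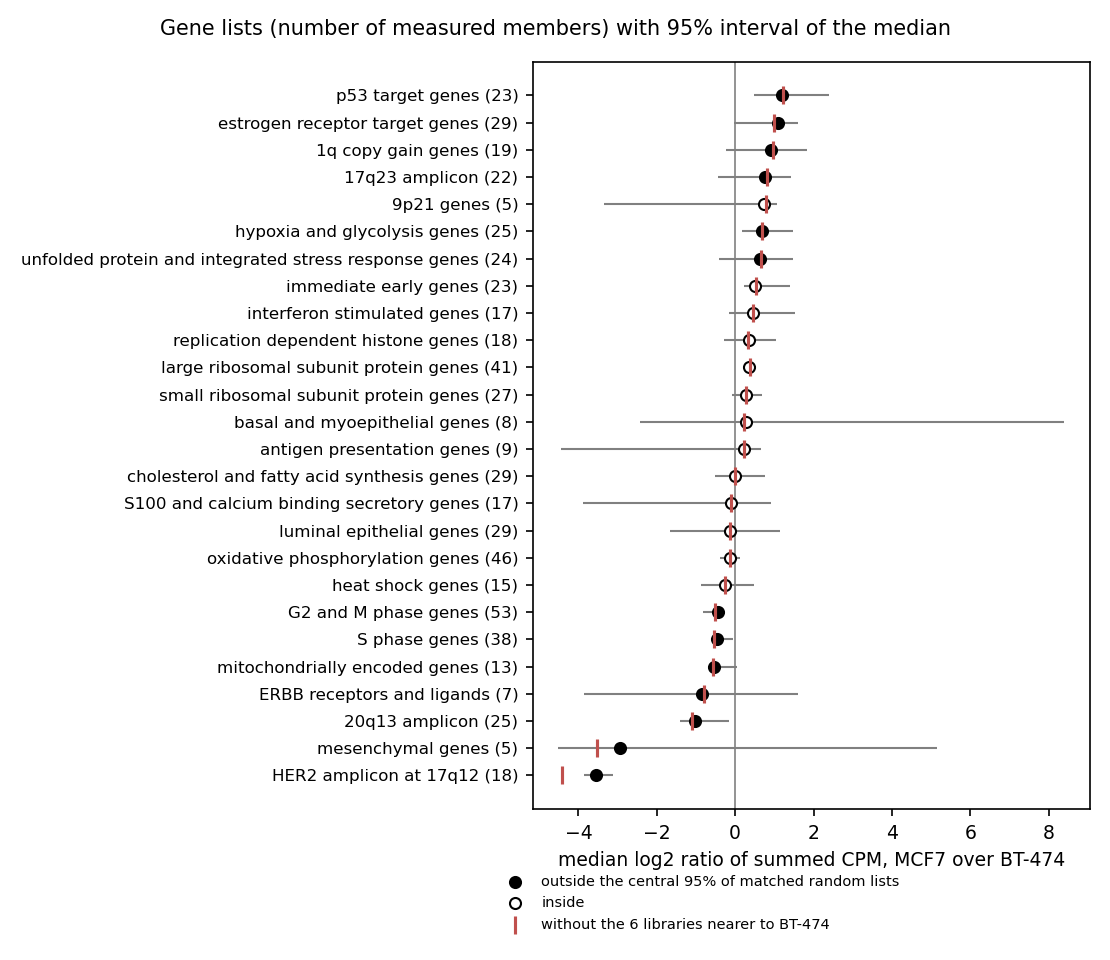
Median log2 ratio of summed CPM, MCF7 over BT-474, of each gene list with at least 5 measured members, with 95% order-statistic intervals. For lists with 5 members the full range is drawn, with coverage under 95%. Filled points lie outside the central 95% of 10000 matched random lists. The HER2 amplicon list lies lowest at -3.56 (-4.41 without the 6 libraries, red mark) and the p53 target list highest at 1.19. Endothelial genes, with 3 members, are not drawn.

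Neighbouring genes differed together in windows of chromosomes 1, 3, 17 and X. The window with the largest difference lay on chromosome 17 from 35578046 to 40093867 and held ERBB2: all 25 genes were higher in BT-474, by a median of 10.7-fold (log2 ratio -3.42, interval -3.70 to -2.88; -4.24 without the 6 libraries; -2.66 with equal weight). A further window of chromosome 17, from 48133440 to 50555852, had all 25 genes higher in BT-474 with STAR (-1.64, interval -2.22 to -1.34), although SKAP1 (-1.46), named for this reason, turned to 4.11 with kallisto and 5.18 with Salmon. Among the 25 were the homeobox genes HOXB13 (-6.47), DLX3 (-3.24) and HOXB7 (-3.15) and B4GALNT2 (-5.35). Between 60043194 and 63843065 of the same chromosome all 25 genes were higher in MCF7 (1.95, interval 1.56 to 2.31), including the collagen receptor MRC2 (7.004, interval 5.77 to 8.63), TBX2-AS1 (4.95), LINC02875 (4.24) and TBX2. On chromosome 1, all 25 genes from 147258885 to 150353195 were higher in MCF7 (2.10, interval 1.53 to 2.497), led by the circadian regulator CIART (6.96), PLEKHO1 (4.87), LINC00624 (3.72) and MTMR11 (3.40). From 112701106 to 117210960 of chromosome 1, 23 of 25 were higher in MCF7 (2.03, interval 1.318 to 2.85), including the GTPase NRAS (3.33), PHTF1 (4.31), HIPK1-AS1 (5.09) and OLFML3, which had 2609 counts in MCF7 and 0 in BT-474 (at least 9.64 on the log2 scale).

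On chromosome 3, 24 of 25 genes from 58505136 to 75679303 were higher in MCF7 (median 1.75, interval 0.89 to 2.24), including the proteasome subunit PSMD6 (4.16), ATXN7 (4.13), EOGT (4.32) and LINC00960, with 1566 counts against 0 (at least 8.90). On chromosome X, 23 of 25 genes from 16786427 to 37847637 were higher in BT-474 (-1.70, interval -1.93 to -1.26), including PTCHD1 (-6.20), RAI2 (-4.43), LINC01456 (-4.44) and the polyamine enzyme SAT1 (-3.09). A mixed window lay on chromosome 20, where 19 of 25 genes from 32762385 to 34927962 were higher in BT-474 (-1.53, interval -3.10 to -0.22; -0.22 with windows of 15 genes), led by the neighbouring BPI-fold genes BPIFA4P (-8.18, interval -10.06 to -6.82), BPIFB2 (-6.56), BPIFA2 (-5.00) and BPIFB1 (-4.90). Without the 6 libraries HOXB13 was at -9.09, B4GALNT2 at -9.33 (interval -11.61 to -7.78), DLX3 at -4.21, HOXB7 at -3.75, PTCHD1 at -8.12 (interval -15.02 to -7.23), RAI2 at -5.18, LINC01456 at -6.98 and BPIFA2 at -8.59 (interval -12.22 to -7.31), and BPIFB2, at 0 counts in MCF7, was at least 506-fold higher in BT-474. With kallisto and Salmon B4GALNT2 was at -2.60 and -2.53, and PTCHD1 at -4.60 and -3.60. The median over 1838 windows was 0.03. With windows of 50 genes the values moved to -1.92 for the ERBB2 window, 1.35 for the NRAS window of chromosome 1, 0.68 on chromosome 3 and -0.90 on chromosome X.

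**Figure D4:**
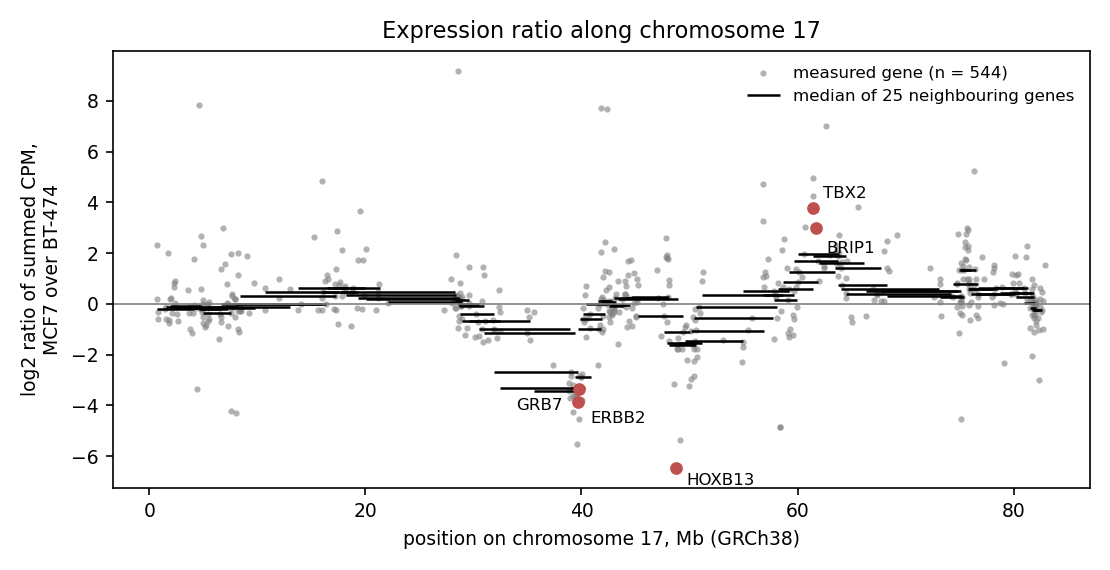
Log2 ratio of summed CPM, MCF7 over BT-474, of measured genes along chromosome 17 (GRCh38 position in Mb), with the median of windows of 25 genes. The window holding ERBB2 lies at -3.42, the window holding HOXB13 at -1.64 and the window holding TBX2 at 1.95.

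GDF15 and TFF3 were among the genes that varied most between MCF7 cells, with and without the libraries nearer to BT-474, and single libraries carried much of this. Relative to the trend on the mean, the log2 excess of the squared coefficient of variation was 6.69 for GDF15, 6.62 for the Wnt inhibitor DKK1 and 5.68 for the trefoil peptide TFF3 across 48 thinned MCF7 libraries. Single libraries held 57.7% of the GDF15 reads (replicate 3), 54.8% of the DKK1 reads (replicate 30) and 30.9% of the TFF3 reads (replicate 96), and without that library the value was 5.07 for GDF15, 2.45 for DKK1 and 4.54 for TFF3. Without MCF7 replicates 3 and 30, which have over 20% mitochondrial counts, GDF15 stood at 5.19 and DKK1 at 2.60. The other 7 of the 10 most variable MCF7 genes were TCN1 (8.12), MDK (6.26), GPX1 (6.15), CRIP1 (5.998), KRT7 (5.97), MIEN1 (4.96) and ALDH3B2 (4.93). None of these 7 was among the 10 without the libraries nearer to BT-474, where MIEN1 fell below the trend (-0.30). The 10 were then GDF15 (6.75), DKK1 (6.71), TFF3 (6.59), the growth factor precursor GRN (5.17), CDKN1A (4.95), MSMB (4.53), CALML5 (4.52), the nuclear RNA NEAT1 (4.43), the protease inhibitor SERPINA3 (4.32) and the p53 target PHLDA3 (4.30). Without the single library with the most reads of the gene, TFF3 then stood at 3.37, DKK1 at 2.41, GRN at 2.21, NEAT1 at 2.59, PHLDA3 at 1.58, CALML5 at 3.05, CDKN1A at 4.16, MSMB at 3.82 and GDF15 at 5.12, and SERPINA3 fell under the minimum mean. Among all kept libraries but replicates 3 and 30, a set that holds the libraries nearer to BT-474, GRN stood at 1.11, NEAT1 at 1.56, PHLDA3 at 1.82 and CDKN1A at 4.27, and SERPINA3 fell under the minimum mean.

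CALML5, MUCL1 and TCN1 varied most between BT-474 cells. Across 58 thinned BT-474 libraries the log2 excess was 5.98 for the calmodulin-like protein CALML5, 5.82 for MUCL1, 5.57 for TCN1, 5.36 for BPIFB1, 5.32 for CXCL14 and 4.63 for DKK1. TCN1 ranged from 6 to 38435 CPM with a median of 501 CPM, and was detected in all 58 libraries. The remaining 4 of the 10 were the ubiquitin-conjugating enzyme UBE2C (4.90), the kinases AURKA (4.75) and PLK1 (4.44), and the activator of the anaphase-promoting complex CDC20 (4.47). Without the library with the most reads of the gene, CALML5 was at 4.42 and CXCL14 at 4.47, and BPIFB1, DKK1 and PLK1 fell under the minimum mean.

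Cell cycle genes varied together between cells of each line. The mean pairwise correlation of S phase genes was 0.567 across MCF7 libraries and 0.736 across BT-474 libraries, and that of G2 and M phase genes was 0.482 and 0.674, each at the 100th percentile of matched random lists. The p53 target genes varied together in MCF7 (0.338, 100th percentile, 21 members) and little in BT-474 (0.048, 97.75th percentile, 17 members); the difference between the lines was not tested. The BT-474 value of p53 targets fell inside the random range with kallisto, Salmon and Spearman correlation. HER2 amplicon genes were at 0.672 in MCF7 and at 0.134, inside the random range (96.9th percentile), without the libraries nearer to BT-474, against 0.075 in BT-474 (99.4th percentile; 96.7th without thinning). Of the scored lists, 12 of 25 in MCF7 and 17 of 26 in BT-474 lay above the central 95% of random lists.

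Cholesterol and fatty acid synthesis genes (0.112 in MCF7 and 0.176 in BT-474), immediate early genes (0.117 and 0.178) and hypoxia and glycolysis genes (0.139 and 0.047, or 0.141 in BT-474 without thinning) were above random in both lines, as were heat shock genes (0.270 and 0.098). Estrogen receptor target genes (0.181), luminal epithelial genes (0.076), replication dependent histone genes (0.104), unfolded protein and integrated stress response genes (0.066) and S100 and calcium binding secretory genes (0.157) were above random in BT-474 and inside the random range in MCF7. The MCF7 value of estrogen receptor target genes, 0.126, rose above the random range without MCF7 replicates 3 and 30 (99.96th percentile), as did those of luminal epithelial genes (99.9th percentile) and of the 17q23 amplicon list (99.1st percentile). Both were also above it by Spearman correlation, as were S100 and calcium binding secretory genes in MCF7 (98.4th percentile), and estrogen receptor target genes without thinning and after the trend removal too, where replication dependent histone genes also were (97.9th percentile). The set without MCF7 replicates 3 and 30 still holds the libraries nearer to BT-474. Without the libraries nearer to BT-474, 0 of the MCF7 lists inside the random range rose above it. In BT-474 the 17q23 amplicon list was above it with kallisto (97.7th percentile) and antigen presentation genes without thinning (99.96th percentile). By Spearman correlation hypoxia and glycolysis genes in BT-474 lay inside the range (97.2nd percentile). In MCF7, cholesterol and fatty acid synthesis genes (93.9th percentile) and immediate early genes (95.5th percentile) fell inside it with log2(CPM + 1), and heat shock genes (96.6th percentile) after a trend on genes detected was removed. The remaining lists above random in both lines were mitochondrially encoded genes (0.674 and 0.417), large ribosomal subunit protein genes (0.658 and 0.382), small ribosomal subunit protein genes (0.610 and 0.385) and oxidative phosphorylation genes (0.430 and 0.154). Without MCF7 replicates 3 and 30, the MCF7 values were 0.485 for mitochondrially encoded, 0.382 for large and 0.351 for small ribosomal subunit protein, 0.136 for oxidative phosphorylation and 0.170 for heat shock genes.

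**Figure D5:**
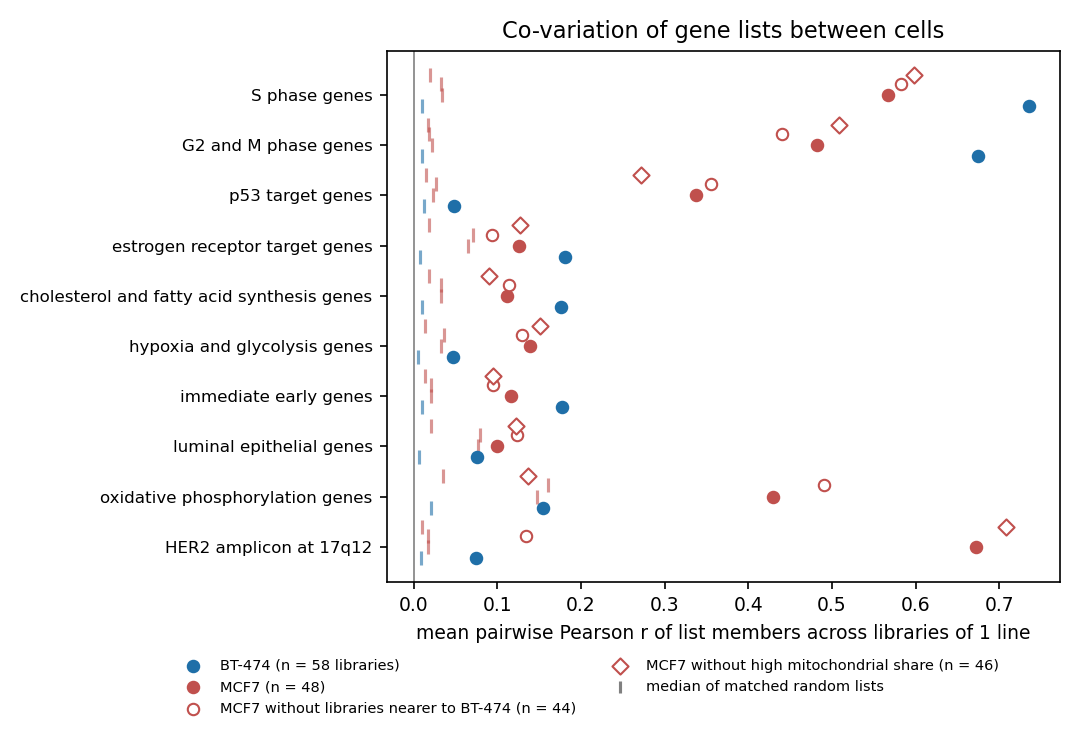
Mean pairwise Pearson correlation of list members across libraries of 1 line, for MCF7, MCF7 without the libraries nearer to BT-474, MCF7 without the libraries of high mitochondrial share, and BT-474, with the median of matched random lists as small marks. S phase genes lie at 0.567 and 0.736 in the lines, and HER2 amplicon genes in MCF7 at 0.672 and 0.134.

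The same libraries gave near-identical profiles with kallisto and Salmon, while abundant genes such as ALDOA, MIF and RPL15 had no counts with STAR. The median correlation per library was 0.988 between kallisto and Salmon (range 0.966 to 0.992), 0.911 between STAR and kallisto (0.847 to 0.919) and 0.896 between STAR and Salmon (0.822 to 0.906). The glycolytic enzyme ALDOA stood at 4355 CPM in kallisto, the cytokine MIF at 2887 CPM, the ribosomal protein genes RPS18 and RPL15 at 2049 and 1919 CPM and the nucleotide kinase NME2 at 1755 CPM. STAR listed 0 counts for ALDOA, MIF, RPL15 and NME2 and 2 for RPS18. The chaperone HSP90AB1, at 1683 CPM in Salmon, also had 0 counts with STAR. Higher in STAR than in kallisto were ENSG00000285382 (126.4 CPM, 231-fold), ENSG00000261832 (120-fold), ENSG00000283765 (80.6-fold), ENSG00000258790 (74.3-fold) and an identifier of the nuclear matrix protein gene MATR3, ENSG00000280987 (20.9-fold). Against Salmon, ENSG00000275300 (at least 7611-fold), ENSG00000284901 (428-fold) and ENSG00000262473 (83.6-fold) joined ENSG00000285382 and ENSG00000283765. Among 8053 genes with 5 CPM or more in all 3 tables, 353 were 2-fold or more apart between STAR and kallisto, 381 between STAR and Salmon and 14 between kallisto and Salmon. Kallisto detected a median of 11708 genes in MCF7 and 11670.5 in BT-474.

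In the authors' deposited table for STAR, ERBB2 had a log2 fold change of -3.75, ESR1 3.25, PGR -3.01 and LGALS1 7.94. The ERBB2 value was -2.89 in the authors' deposited table for kallisto, where ACTB was at 0.33, and -2.86 in the authors' deposited table for Salmon. The log2 fold changes of the authors' deposited table for STAR and the ratios of summed STAR counts correlated across 9739 genes with a Pearson r of 0.923, and 92.5% had the same sign. For Salmon, the authors' deposited table and the ratios of summed Salmon counts correlated with 0.960 across 9508 genes, with 89.6% of the same sign. TMCO1 was at 6.87 and IFT57 at 6.63 in the authors' deposited table for STAR. Their ratios of sums, at the floor of 3 counts in BT-474, were 12.12 and 11.64. ECM1P2 was at 0.00 in the authors' deposited table for STAR.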

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

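The count in near-empty wells was chosen after the data were seen. The 36 near-empty MCF7 wells hold 6104 counts together and enter only the alternative that uses all libraries with any count. In these wells 13 reads fell in the 12 named MCF7-high genes, above the 3 counts that a count of 0 allows. At the median level of 51 MCF7 libraries, 6104 counts would hold 14.1 such reads. The 13 reads came from 7 wells, and 3 of these 7 wells held the 3 reads found in the 12 BT-474-high genes, of which 8.40 would be expected at the median BT-474 level, so the line of this RNA was not determined. In 22 near-empty BT-474 wells, with 1002 counts, 0 reads fell in the MCF7-high genes and 2 in the BT-474-high genes.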

How the results depend on the processing

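Removal of the libraries nearer to the other line, of libraries with over 20% mitochondrial counts and of the library with the most reads of a gene, and thinned gene counts for depth, were chosen after the results were seen. No paired analysis was possible because the comparison of the lines has no test that a block could enter; the same replicate number marks the same well position in both lines. Across 39 positions kept in both lines, the correlation of the libraries' deviations from their line means had a median of 0.024, was over 0.1 in 9, and was the highest among the 72 BT-474 libraries for 1, replicate 58 (0.395). Of 446 recomputed ratios of the genes named for the highest or lowest ratio or for classifying the tumours, 0 changed sign. Of them, 273 stayed within their counting interval and the others moved beyond it. Among genes named elsewhere, SKAP1 turned with kallisto and Salmon. CXCL14 turned in plate columns 7 to 12, where nearly all its MCF7 counts came from libraries nearer to BT-474. H4C8 showed no clear difference in those columns. Of 432 recomputed list medians, 426 stayed within the interval, 3 moved and 3 reversed. This interval over the members is wide for small lists, such as -1.46 to 8.64 for endothelial genes. A median that stayed within it can still change its place against random lists, as that of endothelial genes did with kallisto. TMM scaling shifted the log2 ratios by 0.04 and median-of-ratios scaling by 0.02. The same 6 libraries were nearer to the other line with kallisto and Salmon. ECM1P2 has no value with kallisto or Salmon, and TCN1, MDK, GPX1, CRIP1, KRT7 and ALDH3B2 had none for variability in MCF7 without the libraries nearer to BT-474, since their mean fell under the minimum. Counts of 1 to 10 in the lower line limit the ratios of TMCO1, IFT57, STXBP2, FAS, IFITM1, CT83, MRC2, S100A8, SCGB2A2 and BPIFA4P. Counts under 3 were raised to the floor, as for TMCO1, IFT57, FAS and IFITM1. The same holds for CXCL14, PSAT1, KLK12 and HGD without the libraries nearer to BT-474. Except where the construction of the setting shows it, the cause was not tested.

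Fewer genes pass a stricter definition of detection: at 5 counts the median per library was 8451 in MCF7 and 8520 in BT-474. With kallisto it was 11708 and 11670.5, and with Salmon 11537 and 11588.5. The correlation between the lines was 0.781 at 1 CPM, 0.702 at 20 CPM, 0.755 with kallisto, 0.762 with thinned libraries, 0.771 with equal weight, 0.724 in plate columns 1 to 6, 0.813 with a pseudocount of 1 CPM and 0.657 without the libraries nearer to BT-474. ERBB receptors and ligands reversed to 0.22 with kallisto (4 members), 1.03 with Salmon (3 members) and 1.18 at 20 CPM (3 members), where fewer members were measured. With equal weight of libraries, the medians were -2.79 for the HER2 amplicon list, -0.27 for G2 and M phase genes and -2.66 for the ERBB2 window of chromosome 17. Without the libraries nearer to BT-474 the HER2 amplicon list was at -4.41 and the ERBB2 window at -4.24, and with Salmon that window was at -2.87. Windows of 50 genes, which take in genes beyond each block, gave 1.38 for the TBX2 window of chromosome 17, 1.35 for the NRAS window of chromosome 1, 0.68 on chromosome 3, -1.92 for the ERBB2 window, -0.90 on chromosome X and -1.19 for the HOXB13 window, and windows of 15 genes gave -0.22 on chromosome 20. Without the libraries nearer to BT-474, 3 of the 10 most variable MCF7 genes were shared with the ranking of all kept libraries, and MIEN1 reversed to -0.30. The agreement per library among genes of 5 CPM or more in all 3 tables was 0.964 for STAR and kallisto, 0.962 for STAR and Salmon and 0.996 for kallisto and Salmon, and with a pseudocount of 10 CPM it was 0.921 and 0.907 for the pairs with STAR.

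For the co-variation of the 12 MCF7 and 17 BT-474 lists above the random range, each mean correlation that moved by more than 1 SD of the matched random lists is given by setting. Lists inside that range are not included. By Spearman correlation, MCF7 had HER2 amplicon 0.285, S phase 0.587, p53 target 0.282, hypoxia and glycolysis 0.0927, heat shock 0.195, mitochondrially encoded 0.515, large ribosomal 0.484, small ribosomal 0.408 and oxidative phosphorylation 0.217, and BT-474 had estrogen receptor target 0.163, immediate early 0.161, large ribosomal 0.361, oxidative phosphorylation 0.120 and histone 0.0704. After removal of a trend on log10 genes detected, MCF7 had S phase 0.547, G2 and M phase 0.468, heat shock 0.169, large ribosomal 0.595 and oxidative phosphorylation 0.331, and BT-474 had G2 and M phase 0.634. With kallisto, MCF7 had HER2 amplicon 0.728, hypoxia and glycolysis 0.235 and immediate early 0.152, and BT-474 had G2 and M phase 0.683, cholesterol and fatty acid synthesis 0.202, unfolded protein and integrated stress response 0.0967 and oxidative phosphorylation 0.140. With Salmon, MCF7 had HER2 amplicon 0.745, hypoxia and glycolysis 0.247, immediate early 0.153 and oxidative phosphorylation 0.378, and BT-474 had estrogen receptor target 0.162, S phase 0.724, unfolded protein and integrated stress response 0.0909 and immediate early 0.157. On the scale of log2(CPM + 1), MCF7 had HER2 amplicon 0.524, S phase 0.537, G2 and M phase 0.443 and p53 target 0.272, and BT-474 had S phase 0.695, G2 and M phase 0.643, immediate early 0.149 and histone 0.0743. Without thinning, MCF7 had HER2 amplicon 0.729, G2 and M phase 0.495, hypoxia and glycolysis 0.167 and large ribosomal 0.599, and BT-474 had estrogen receptor target 0.149, luminal epithelial 0.0970, S phase 0.726, cholesterol and fatty acid synthesis 0.193, unfolded protein and integrated stress response 0.0892, hypoxia and glycolysis 0.141, immediate early 0.203, large ribosomal 0.410, small ribosomal 0.408 and oxidative phosphorylation 0.133. Leaving out the libraries nearer to BT-474 gave MCF7 values of 0.134 for HER2 amplicon, 0.440 for G2 and M phase, 0.738 for large ribosomal and 0.491 for oxidative phosphorylation. Leaving out the MCF7 libraries with over 20% mitochondrial counts gave HER2 amplicon 0.707, S phase 0.597, G2 and M phase 0.508, p53 target 0.271, cholesterol and fatty acid synthesis 0.0902, heat shock 0.170, mitochondrially encoded 0.485, large ribosomal 0.382, small ribosomal 0.351 and oxidative phosphorylation 0.136.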

Other observations

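Chosen after the result was seen were the tests on the libraries labelled MCF7 that resemble BT-474, the tests of p53 target co-variation against genes detected and against those libraries, and the permutations of libraries between lists. In MCF7, the p53 target list tended to vary against the G2 and M phase list. Without the libraries nearer to BT-474, the mean correlation between members of the p53 target list and of the G2 and M phase list was -0.126 across 44 MCF7 libraries, just outside the central 95% of 10000 permutations of the libraries of 1 list (2.06th percentile). It was -0.157 with all 48 libraries (0.35th percentile) and -0.147 without MCF7 replicates 3 and 30 of high mitochondrial share (0.45th percentile). Both of these sets hold libraries nearer to BT-474. The p53 target list was higher in MCF7 (median log2 ratio 1.19) and the G2 and M phase list higher in BT-474 (-0.43). Such libraries alone would push the correlation below 0, so both values add no separate evidence. With the S phase list it was -0.071, inside that range (17.1st percentile). In BT-474 the values were 0.052 with G2 and M phase genes, inside the range (92.6th percentile), and 0.077 with S phase genes (98.3rd percentile). The S phase and G2 and M phase lists correlated with each other at 0.404 in MCF7 and 0.419 in BT-474. The difference between the lines was not tested.

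The p53 target genes varied together in MCF7 at a mean correlation of 0.338. The tables argue against a difference in detected genes as the whole cause, since the value was 0.351 after a trend on genes detected was removed. They also argue against the libraries nearer to BT-474 alone (0.355 without them) and against MCF7 replicates 3 and 30 of high mitochondrial share alone (0.271 without them), each at the 100th percentile of random lists. These groups were not removed together, so both together as the cause stay open. The opposite variation with G2 and M phase genes, -0.126, lies close to the edge of the permuted range, and the labels name no separate cultures. A candidate explanation, a hypothesis found on these cells, is that some MCF7 cells held active p53 and had left the cell cycle; neither was measured, and staining of p53 protein and of a proliferation marker in the same cells would test it.

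Of the 6 libraries labelled MCF7 that were nearer to BT-474, 5 held a median of 0.833% of the MCF7-high level, which argues against an MCF7 cell with some BT-474 RNA added. BT-474 RNA in place of MCF7 RNA stays open, as does a whole swap of wells: 0 of the 5 BT-474 libraries in the same wells were kept and nearer to MCF7, but 4 of these hold 24 counts or fewer and cannot be assigned to a line (the fifth, with 17583 counts, was nearer to BT-474, 0.741 against 0.552), and the highest MCF7-high level among the 5 was 2.15%, inside the range of the BT-474 libraries (up to 5.10%). All 5 BT-474 libraries of the same wells were among the 23 of 95 not kept, which 5 wells drawn at random would give with a probability of 0.000581, so material of the same BT-474 well may have entered the MCF7 well or library, or a filled BT-474 well may have been swapped with a near-empty MCF7 well. The sixth library, replicate 58, held at least 31.4% of each line's level and may hold RNA of both lines; the kept BT-474 library of its well had the highest correlation with its remaining variation of all 72 (0.549). No biological explanation was tested.

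Of 2917 genes with 50 CPM or more in both kallisto and Salmon, 243 stood under 1% of that level in STAR and 17 of these were not listed; they held 7.32% of the kallisto CPM and include ALDOA, MIF and RPL15. Exons shared with another gene were annotated for 71.6% of them against 52.7% of the other 2674 genes. This was under the ratio of 1.5 predicted for this cause, but the share in the other genes leaves little room for that ratio. The overlaps came from the annotation used here for gene order, and the release behind the STAR counts is not given. The 69 genes without such an overlap may share exons in that release, so shared exons stay open as part or the whole of the cause. A pseudogene named after the gene was annotated for 25.5% against 24.5%, also under the ratio of 1.5 predicted for this cause. Only pseudogenes named as the gene with P and a number were counted, so copies with other names were missed. The treatment of reads with several matches is not given either, so pseudogene copies stay open too. No biological explanation was tested, since the same libraries were quantified each time.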
